A study of Mus musculus with 20 samples.

How the data were processed

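The deposited table held whole-number read counts for 19269 gene symbols in 20 libraries, not normalised. Per the submitters' processing notes, the tools used upstream were FastQC 0.11.3, TopHat2 2.0.13, Bowtie2 2.2.1, Cufflinks, Cuffdiff 2.1.1, HTSeq 0.6.1 and DESeq2 1.14.1, with the mouse build mm10. The role of each tool, the gene annotation and the strand setting of the counting were not given in the sources used here. Per the labels' protocols, polyA RNA was isolated with a micro-column kit and DNase treatment and amplified with a SMARTer v4 ultra-low-input kit. Without a stated strand setting, reads of overlapping or antisense genes could not be told apart, and genes with near-identical copies, such as ribosomal protein genes, Actb, haemoglobin and major histocompatibility genes, are uncertain. Handling of duplicate reads was not given in the sources used here, so the detection floors given here cover counting error only.

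Groups were taken from the sample titles. Titles and fraction labels separated the immunoprecipitate (IP) from the depleted supernatant, young from adult, and GFP-negative from GFP-positive mice. The series text named 4 pools as taken from an earlier series; these are called prior pools, and their earlier and repeated libraries the first and second sequencing sets. All 16 other and repeated libraries belonged to the second set. The series text named the GFP-positive supernatant differently in 2 places, once as the library titled adult negative 1. The sample titles and genotypes were followed. Replicate numbers followed the titles, although the descriptions of the adult negative supernatants gave other numbers. Per the labels, young negative pools 1 and 2 were wild type and pool 3 carried the floxed L10a-GFP allele alone, while both adult negative pools carried GnRH-Cre alone. Age and genotype therefore changed together among the negative pools. Any prenatal treatment of the prior pools was not given in the labels used here.

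Total counts ran from 27.7 to 50.5 M per library, from 27.7 to 50.5 M in the 14 supernatant libraries and from 34.4 to 49.6 M in the 6 IP libraries. A floor of 3 counts lay between 0.0594 and 0.108 counts per M (CPM). Between 13549 and 14165 genes per library exceeded 1 CPM. Genes with any count numbered 15120 to 16002 in the IP libraries and 17078 to 17720 in the supernatants. No pair of libraries was identical. Log2 CPM of the same pool in both sequencing sets correlated at 0.975 to 0.980 across genes, supernatants of the same group at 0.970 to 0.990 and negative IP libraries of the same group at 0.891 to 0.910. Genes are not independent replicates, so no p-value was attached to these correlations.

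Differential expression was tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with trimmed-mean (TMM) scaling, the filterByExpr filter (minimum count 10) and Benjamini-Hochberg adjustment over the genes tested, at a threshold of 0.05. One fit of the 10 negative-control libraries (6 residual degrees of freedom) gave the contrasts of IP with supernatant, of age within the IP, and of age by fraction. A second fit held 1 second-set supernatant library from each of 10 pools, with age and pool origin as terms (7 residual degrees of freedom). A further fit compared the second with the first sequencing set in 8 libraries of 4 pools, with the pool as a term. The last fit held the 6 IP libraries; the lone GFP-positive library was assumed to vary like the negative ones. CPM values in the text are means of TMM-scaled values over the libraries of the fit unless stated, with the SD. Named genes were the 8 with the largest log2 fold change in each direction among genes past the threshold, with mean log2 CPM of at least 3 and every library of one group above every library of the other. Symbols of predicted genes were left out, and Gnrh1 and Rpl10a were always followed. For the GFP-positive IP, a descriptive count took genes at 1 CPM or more that were at least 2-fold above the own supernatant and above every negative IP library. The same count was made for each negative IP library.

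Gene groups were tested with camera in limma 3.58.1 at a preset correlation of 0.01, adjusted over the groups within a comparison, and again with an estimated correlation. Of 30 lists, 29 had a member in the table; the list of mitochondrially encoded genes had none. Lists with fewer than 3 measured members were not tested. The comparisons, the gene lists, the rule for named genes and most of the other settings tried were chosen before the data were examined. Transcript length and GC content came from the annotation of the mouse build GRCm38, the assembly also called mm10, for 18961 genes, 98.4% of the table. They are those of the longest annotated transcript of each gene, protein-coding where there was one, which need not be the one expressed. Gene coordinates came from the same source.

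The numbers of the negative pools pair each IP with its own supernatant, since per the labels both fractions were taken from the same pool. Deviations from the group means correlated at 0.28, 0.18 and 0.434 across genes for the young pairs and at 0.21 for the adult pairs. The pool was therefore entered as a block in an alternative fit. Other alternatives were relative-log-expression (RLE) scaling, no filter on low counts, DESeq2 1.42.0, limma voom with quality weights, leaving out each library in turn, other covariates or subsets for age, and other thresholds for the descriptive count. The edgeR, limma and DESeq2 steps were tested on simulated counts with 200 changed genes. Each gene was given the same spread in every library of a fit, without differences between pools. The real IP libraries varied more than the supernatants and were paired with them. The simulated false calls for IP against supernatant therefore need not hold for the data. Age within the IP and age by fraction were not simulated. For IP against supernatant, edgeR recovered 72% of 2-fold and 91% of 4-fold changes with 8 unchanged genes called among 16361, where DESeq2 called 79. For age in supernatant edgeR recovered 98% and 100% with 11 false calls among 15938, and DESeq2 made 33. For the sequencing sets it recovered 100% of both sizes with 16 false calls among 16117. For the GFP-positive IP it recovered 2% of 2-fold and 49% of 4-fold changes with 6 false calls among 16586, where DESeq2 made 155. Libraries of the earlier series other than the 4 first-set repeats were not analysed here. A few single results were left out and are not reported here.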

Results

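The libraries came from punches of the preoptic area, the part of the hypothalamus that holds most gonadotropin-releasing hormone (GnRH) neurons, in female mice at day 21 (young) or days 70 to 150 (adult, in diestrus). Tissue of 3 to 4 mice was pooled for each sample. The assay was translating ribosome affinity purification, in which ribosomes that carry a GFP-tagged L10a subunit are pulled down together with the mRNA they hold. The cross of GnRH-Cre with floxed L10a-GFP mice places the tag in GnRH neurons. The 5 negative-control pools, 3 young and 2 adult, came from mice without the tag, and each gave an IP and a depleted supernatant. An adult GFP-positive pool gave the same fractions as a positive control without replicate. Supernatant RNA of 4 GFP-positive pools of the earlier series, 2 young and 2 adult, was present from both sequencing sets, which made 20 libraries of 27.7 to 50.5 M counts each. Pools were taken to hold separate mice, so the p-values refer to the spread between pools of a group. Between sequencing sets they refer to repeats of the same RNA. The main fit of the negative controls did not pair the IP with the supernatant of the same pool, which only the alternative fit with the pool as a block did. For the lone GFP-positive IP the spread was that of the negative IP libraries.

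The first question was which transcripts a pull-down without tagged ribosomes recovers. Prr12, which encodes a proline-rich nuclear protein, stood at 1335 ± 215 CPM in the negative IP against 12.6 ± 2.88 CPM in the supernatant (SD, n = 5 each), 104-fold higher (log2 6.70, SE 0.22, adjusted p = 6.48e-08). It lies on chromosome 7 from 45027563 to 45052881 (mm10). Bahcc1, a chromatin protein gene, rose by log2 6.62 (SE 0.17), and Bcor, which encodes a corepressor that binds BCL6, by 6.61 (SE 0.20). Tnrc18 rose by log2 6.34 (SE 0.19) to 1557 ± 494 CPM, and Mn1, a transcriptional coregulator gene, by 5.70 (SE 0.21) to 1916 ± 588 CPM. Gse1 (log2 5.69, SE 0.20), Rai1 (5.59, SE 0.24) and Yeats2 (5.36, SE 0.30), which encodes a reader of acylated histones, completed the 8 rises named by rule. Steeper changes of rarer transcripts, such as Stra8 (log2 6.07, SE 1.43), lie outside that rule.

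Of the falls named by the same rule, that of Lars2, the mitochondrial leucyl-tRNA synthetase gene, was the largest. Lars2 went from 12664 ± 3124 CPM in the supernatant to 1018 ± 315 CPM in the IP (log2 -3.60, SE 0.21, n = 5 each). Malat1, a long noncoding RNA retained in nuclei, fell by 1.83 on the log2 scale (SE 0.10), from 6172 ± 1448 to 1628 ± 194 CPM. The list of nuclear long noncoding RNAs did not follow it, with 4 of 10 up and 2 down (5 and 2 adjusted over the list alone), a median of 0.67 and adjusted p = 0.494. Eef1a2, a translation elongation factor gene, changed by log2 -1.85 (SE 0.11) and Rps29, a ribosomal protein gene, by -1.65 (SE 0.20). Bri3 (-1.96, SE 0.25), Sepx1 (-1.74, SE 0.25), Raly (-1.65, SE 0.16) and Fbll1 (-1.64, SE 0.15) fell as well. Whether reads of ribosomal RNA repeats were counted at Lars2 was not tested.

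Genes of the respiratory chain and of the ribosome were lower in the negative IP as groups. Across all genes the ratio of IP to supernatant ran with transcript length (rank correlation 0.601). No list was tested with that trend removed, so how far length accounts for the changes of these and the following lists is not known. Of 77 nuclear genes of oxidative phosphorylation, 64 fell and 1 rose (65 and 1 adjusted over the list alone), led by Atp5g3 (log2 -1.22, SE 0.10) and Cox5a (-1.10, SE 0.10), with Ndufs1 going the other way (0.53, SE 0.08). For this list camera gave an adjusted p = 7.09e-27, and adjusted p = 0.604 with an estimated correlation. Of 78 cytosolic ribosomal protein genes, 73 fell (75 adjusted over the list alone), among them Rpl23 (-1.21, SE 0.13) and Rps13 (-1.03, SE 0.12). Their camera value was adjusted p = 2.46e-24, and adjusted p = 0.604 with an estimated correlation. Of 15 glutamate receptor subunit genes 9 rose (10 adjusted over the list alone), including the NMDA receptor genes Grin1 (137 ± 18.1 against 62.5 ± 6.52 CPM) and Grin2b (log2 1.32, SE 0.21), at adjusted p = 0.00132, and adjusted p = 0.278 with an estimated correlation. Neurofilament genes Nefl (1.89, SE 0.11) and Nefm (1.28, SE 0.09) rose while Snap25 (-0.55, SE 0.09) and Stmn2 (-0.55, SE 0.08) fell, so that the pan-neuronal list had 4 genes up and 2 down of 12 (4 and 2 adjusted over the list alone) and did not pass (adjusted p = 0.064). Collagen and basement membrane genes had 3 of 13 up (3 adjusted over the list alone), Col4a1 (2.11, SE 0.40), Lamc1 (1.77, SE 0.28) and Col4a2 (1.58, SE 0.31), at adjusted p = 0.0779. With the pool as a block the collagen list passed at adjusted p = 0.0271, and it had adjusted p = 0.792 with an estimated correlation in the fit without the block. Among immediate early genes Btg2 rose (2.55, SE 0.17), with 3 of 11 members up (3 adjusted over the list alone) and adjusted p = 0.0752. Markers of microglia (3 down and 0 up of 12, Siglech lowest at -6.39, SE 1.00) and astrocytes (2 up and 1 down of 12) gave camera values of 0.626 and 0.69, and the same counts adjusted over the list alone. Gnrh1 was not higher in the negative IP (log2 -0.70, SE 0.25, adjusted p = 0.057), and in young pools it fell (-1.30, SE 0.33, adjusted p = 0.0135).

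**Figure D1:**
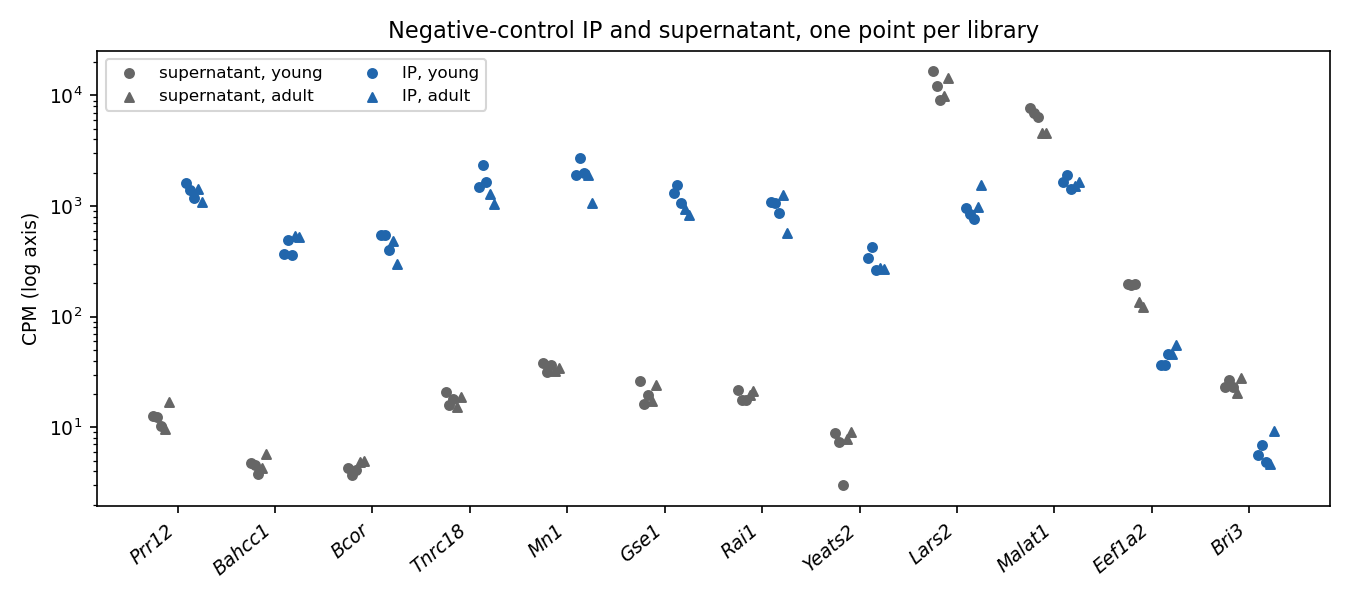
TMM-scaled CPM on a log axis for 12 genes, with 1 point per library of the 5 negative-control pools; grey marks supernatant, blue marks IP, circles young and triangles adult. All 5 IP points of Prr12, Bahcc1, Bcor, Tnrc18, Mn1, Gse1, Rai1 and Yeats2 lie above their 5 supernatant points, and the reverse holds for Lars2, Malat1, Eef1a2 and Bri3.

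In total 2593 genes rose and 2653 fell of 16361 tested by edgeR, and longer transcripts stood higher in the IP, with a median log2 ratio of -0.51 among the shortest (up to 1843 nt) and 0.70 among the longest (from 5359 nt). The rank correlation with length was 0.601 across 10681 genes, which are not independent replicates, and that with GC content was -0.006. Young pools gave 2128 rises and 2300 falls and adult pools 1045 and 734. The young count of 4428 was 2842 without young supernatant 2. The adult count of 1779 was 1185 without that library, 285 and 485 without adult supernatants 1 and 2, 887 without adult IP 1, and 2897 by DESeq2. Fold changes of the age groups, which share no libraries, correlated at 0.832 across 10770 genes. Of 1591 genes called at both ages 1590 had the same sign, with 956 rising in both where independent lists would share 135.9 and 634 falling in both where they would share 103.2. The calls of both ages rest on a spread estimated in the same fit, so the lists were not independent. The size of their overlap can therefore not be judged against these expected numbers. For the genes named over both ages, the rule that chose them fixed the direction at each age. Prr12 rose by log2 6.84 (SE 0.26, n = 3 each) in young and 6.55 (SE 0.32, n = 2 each) in adult pools. Bcor rose by 6.91 (SE 0.25) and 6.31 (SE 0.29), Bahcc1 by 6.52 (SE 0.20) and 6.71 (SE 0.25), and Lars2 changed by -3.93 (SE 0.26) and -3.28 (SE 0.31).

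In the adult pools alone 6 lists passed. Oxidative phosphorylation fell (34 down and 1 up of 77, 62 and 1 adjusted over the list alone; adjusted p = 8.49e-17, and adjusted p = 0.584 with an estimated correlation), as did ribosomal proteins (10 of 78 down, 59 adjusted over the list alone; adjusted p = 1.28e-15, and adjusted p = 0.76 with an estimated correlation). Glutamate receptor subunits (3 of 15 up, 5 adjusted over the list alone), pan-neuronal genes (3 up and 1 down of 12, 3 and 2 adjusted over the list alone) and perineuronal net genes (1 of 10 up, Ptprz1 at 1.27, SE 0.20; 1 adjusted over the list alone) each had adjusted p = 0.0472, and adjusted p = 0.584 with an estimated correlation. Collagens (2 of 13 up, 2 adjusted over the list alone) also had adjusted p = 0.0472, and adjusted p = 0.76 with an estimated correlation. With the pool as a block the pan-neuronal list no longer passed (adjusted p = 0.0617), and GABA neuron markers passed (adjusted p = 0.0318 against 0.177 without the block). Without the block both had adjusted p = 0.584 with an estimated correlation. In young pools ribosomal proteins (73 of 78 down, 74 adjusted over the list alone) had adjusted p = 3e-29, and adjusted p = 0.666 with an estimated correlation. Young oxidative phosphorylation genes (62 down and 1 up of 77, 64 and 1 adjusted over the list alone) had adjusted p = 7.67e-33, and adjusted p = 0.51 with an estimated correlation. Young glutamate receptor subunits (10 of 15 up, 10 adjusted over the list alone) had adjusted p = 0.000116, and adjusted p = 0.15 with an estimated correlation.

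Whether the nonspecific pull-down differed between ages was tested as an interaction. Age and genotype changed together in these pools, so the interaction cannot separate them. No single gene passed by edgeR, with 1068 genes at an unadjusted p under 0.05, none by limma voom and 118 by DESeq2. Without adult IP 2, edgeR called 67. At the preset correlation 4 lists passed with small median shifts, and with an estimated correlation none did. The IP over supernatant ratio was higher in adults by a median of log2 0.44 over 77 oxidative phosphorylation genes (adjusted p = 1.9e-14, and adjusted p = 0.939 with an estimated correlation) and of 0.41 over 78 ribosomal protein genes (adjusted p = 3.09e-12, and adjusted p = 0.939 with an estimated correlation). It was lower by -0.46 over 15 glutamate receptor subunit genes (adjusted p = 0.00591, and adjusted p = 0.412 with an estimated correlation) and by -0.32 over 14 cholesterol synthesis genes (adjusted p = 0.0347, and adjusted p = 0.939 with an estimated correlation). With the pool as a block immature neuron genes (adjusted p = 0.0234 against 0.0857) and blood genes (0.0227 against 0.0895) passed too. Without the block both had adjusted p = 0.939 with an estimated correlation. The interaction also ran with transcript length, with a rank correlation of -0.258 across 10681 genes, which are not independent replicates, and a median of 0.23 among the shortest and -0.08 among the longest.

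The GFP-positive pool tested the pull-down itself. Gnrh1, which encodes the GnRH precursor and lies on chromosome 14 from 67745181 to 67749439, stood at 1451 CPM in the GFP-positive IP against 28.2 CPM in its supernatant, 51.4-fold higher, and against 15.5 ± 9.84 CPM (SD, n = 5) in the negative IP libraries, the highest of which held 32.3 CPM. These values were scaled over the 12 libraries of the new pools. The series text in 1 place named another library, adult negative supernatant 1, as the GFP-positive supernatant; the sample labels were followed. Scaled over 20 libraries these supernatants held 27.3 and 28.2 CPM of Gnrh1, but the descriptive count and the list medians against the supernatant rest on this choice. So do the comparisons that use adult negative supernatant 1, which is 1 of only 2 adult negative supernatants. The spread of the GFP-positive IP is unknown, as there was 1 such library. On the assumption that it varied like the negative ones, edgeR called Gnrh1 alone of 16586 genes against the adult negative IP (log2 5.91, SE 0.44, adjusted p = 0.0214, 1 library against 2), with 821 genes at an unadjusted p under 0.05, 1 by limma voom and 210 by DESeq2. The fold change stayed between log2 5.49 and 6.51 when 1 negative library was left out, but the call ended without young IP 1 (adjusted p = 0.11), young IP 2 (0.142), adult IP 1 (0.0609) or adult IP 2 (0.117). Rpl10a, the gene of the ribosomal protein that carries the tag, stood at 91.0 CPM in the GFP-positive IP, 118 CPM in its supernatant and 91.7 ± 17.8 CPM in the negative IP. Kiss1r, the kisspeptin receptor gene, stood at 18.8 CPM in the GFP-positive IP against 6.72 CPM in its supernatant, and the highest negative IP library held 16.7 CPM.

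**Figure D2:**
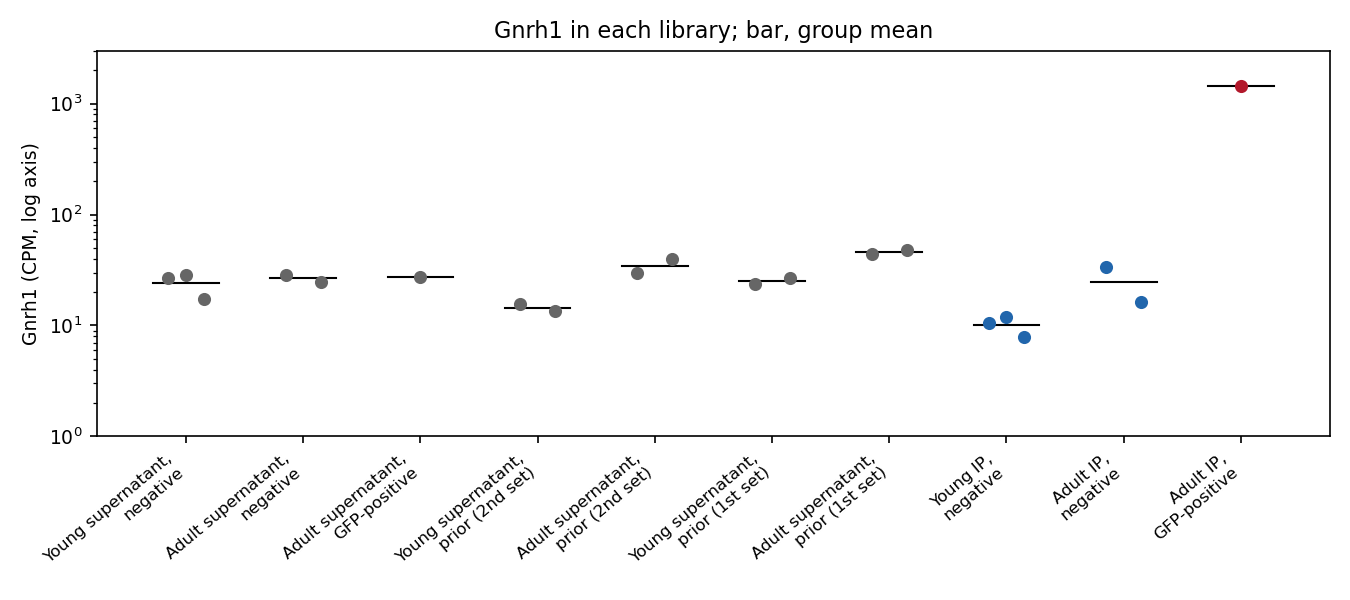
Gnrh1 CPM on a log axis in each of the 20 libraries, scaled over all of them, by group; red marks the GFP-positive IP, blue the negative IP and grey the supernatants, and the bar is the group mean. The GFP-positive IP lies at 1457 CPM and every other library between 7.85 and 47.6 CPM.

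Transcripts that rose in the pull-down without the tag were abundant in the GFP-positive IP as well. Prr12 stood at 615 CPM there against 11.3 CPM in the supernatant of the same pool, Bahcc1 at 236 against 4.24 CPM, Mn1 at 1330 against 36.1 CPM and Tnrc18 at 717 against 14.8 CPM; the negative IP means were 1299, 446, 1862 and 1515 CPM. By the descriptive count, 152 genes were at least 2-fold above the own supernatant and above the 5 negative IP libraries in the GFP-positive IP. The same count over each negative IP library gave 228 to 277 genes with 1 fewer library to exceed, so the number itself did not set the GFP-positive IP apart. Of the 10 genes with the largest fold in that count, Gnrh1 was the only one above 3.15 CPM. BC055402, Gdf6, 1700029M20Rik, Slc44a4, Cnksr1, Gja10, 1300002K09Rik, Fndc3c1 and Gm4759 stood at 1.84 to 3.15 CPM in this 1 library and at 0.04 CPM or less in its supernatant and the 5 negative IP libraries. Over the whole count, 33 of the 152 genes, Gnrh1 among them, stood at 5 CPM or more, against 67 to 124 in the negative IP libraries.

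Gene groups of the GFP-positive IP are given as measured against the adult negative IP, since an arm of 1 library cannot carry a test of a group. Only some of the lists are given, so they do not stand for all lists. Beside Gnrh1, the GnRH neuron markers differed by log2 0.92 (Gal, SE 0.47), 1.57 (Kiss1r, SE 1.00) and -1.23 (Esr2, SE 2.76), with standard errors taken from the spread of the negative libraries. The median log2 difference was 0.34 over 12 pan-neuronal genes. It was -0.71 over 12 genes of mature oligodendrocytes (Mbp at -1.67, SE 0.65), -1.09 over 10 complement and MHC class I genes, -0.45 over 10 nuclear long noncoding RNAs (Malat1 at -1.19, SE 0.22) and -1.40 over 13 collagen and basement membrane genes. Within the GFP-positive pool, the median log2 ratio of IP to supernatant was 0.75 over glutamate receptor subunits, above 99.9% of 10000 random lists matched on expression, and -0.77 over ribosomal proteins and over oxidative phosphorylation genes, at the 0 percentile for both. In the adult pull-down without the tag the same medians were 0.48, -0.69 and -0.73, so these shifts were not particular to the tagged IP. The secretory pathway stood at 0.44 (99.6%), against 0.28 without the tag, pan-neuronal genes at 0.34 (99.8%), against 0.19, and immature neuron genes at 0.39 (97.3%), against 0.41. GnRH neuron markers stood at 0.83 (96.1%), against -0.07, and fibroblast and meningeal markers at -0.51 (2.99%), against 0.25. These percentiles describe 2 libraries only.

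The supernatants gave a comparison of adult with young preoptic area over 5 pools per age. Serpinb1a, a serine protease inhibitor gene, rose from 2.03 ± 0.52 CPM to 16.7 ± 5.32 CPM (log2 3.05, SE 0.19, adjusted p = 1.69e-06), and Il33, which encodes a nuclear cytokine, from 12.2 ± 4.51 to 75.4 ± 10.6 CPM (2.68, SE 0.15). Kiss1, the kisspeptin gene on chromosome 1 from 133321875 to 133329901, rose from 4.42 ± 2.12 to 17.5 ± 7.10 CPM (1.93, SE 0.34, adjusted p = 0.0045). Neat1, a long noncoding RNA, rose by log2 1.63 (SE 0.19), Hapln2, a link protein gene of the nodal matrix, by 1.57 (SE 0.21), and Trf, the transferrin gene, by 1.56 (SE 0.20). Arsg (1.34, SE 0.20) and Upp2 (1.30, SE 0.21) rose as well. Gpr17, a receptor of immature oligodendrocytes, fell from 34.4 ± 5.89 to 11.4 ± 2.04 CPM (log2 -1.60, SE 0.13), and Mobp, a myelin protein gene, from 574 ± 159 to 198 ± 69.5 CPM (-1.54, SE 0.16), although adult negative pool 2 held 322 CPM. Rras2 (-1.58, SE 0.15), Rnf122 (-1.58, SE 0.16), Enpp6 (-1.47, SE 0.27), which marks newly formed oligodendrocytes, Col9a3 (-1.44, SE 0.16), Zfp41 (-1.26, SE 0.14) and Traf3 (-1.24, SE 0.13) fell too.

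Groups higher in adults included immune and peptide genes. Of 10 complement and MHC class I genes 6 rose (8 adjusted over the list alone), such as H2-T23 (log2 1.31, SE 0.17) and Psmb8 (1.33, SE 0.20), at adjusted p = 4.1e-08, and adjusted p = 0.167 with an estimated correlation. Of 12 microglia markers 5 rose (7 adjusted over the list alone), led by Ctss (1.24, SE 0.19), C1qb (0.73, SE 0.15) and C1qa (0.86, SE 0.21), at adjusted p = 0.00011, and adjusted p = 0.371 with an estimated correlation. Of 24 hypothalamic neuropeptide genes 6 rose and 1 fell (8 and 1 adjusted over the list alone). Besides Kiss1, the opioid precursor genes Penk (0.70, SE 0.13) and Pdyn (0.83, SE 0.18), Cartpt (0.65, SE 0.14) and Tac1 (0.68, SE 0.15) rose, and Pomc went the other way (-0.64, SE 0.18). The neuropeptide list had adjusted p = 3.91e-05, the peptide secretory pathway (4 of 12 up, 7 adjusted over the list alone; Scg5 at 0.52, SE 0.13) adjusted p = 0.000112 and GABA-A receptor subunits (3 of 14 up, 6 adjusted over the list alone; Gabra3 at 0.54, SE 0.09) adjusted p = 2.82e-05, each with adjusted p = 0.368 with an estimated correlation. Glutamate receptor subunits (3 of 15 up, 3 adjusted over the list alone; Gria1 at 0.56, SE 0.11) had adjusted p = 0.00223, and adjusted p = 0.494 with an estimated correlation. Astrocyte markers (1 of 12 up, Slc1a3 at 0.41, SE 0.10; 3 adjusted over the list alone) had adjusted p = 0.045, and adjusted p = 0.368 with an estimated correlation. Ribosomal protein genes (5 up and 1 down of 78, 3 and 1 adjusted over the list alone) moved by a median of 0.10 at adjusted p = 0.00122, and adjusted p = 0.784 with an estimated correlation.

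Other groups were lower in adults. Immature neuron genes fell in 5 of 12 (5 adjusted over the list alone), among them Marcksl1 (log2 -1.04, SE 0.07), Dpysl3 (-0.56, SE 0.08) and Sox4 (-0.52, SE 0.10), at adjusted p = 4.43e-06, and adjusted p = 0.167 with an estimated correlation. Cell cycle genes fell in 4 of 9 (4 adjusted over the list alone), with Cdk1 at -1.89 (SE 0.39) and Top2a at -1.41 (SE 0.40), at adjusted p = 0.00145, and adjusted p = 0.167 with an estimated correlation. In the oligodendrocyte precursor list 3 of 8 genes fell (3 adjusted over the list alone), namely Gpr17, Enpp6 and Neu4 (-0.70, SE 0.11). That list had adjusted p = 4.21e-05, and adjusted p = 0.167 with an estimated correlation. Gpr17 and Enpp6 belong to immature or newly formed oligodendrocytes, and Pdgfra and Cspg4 of the same list were not among the falls. A fall of the precursors themselves was therefore not shown. Mature oligodendrocyte genes fell in 4 of 12, including Cnp (-0.86, SE 0.13) and Mbp (-0.65, SE 0.16); adjusted over the list alone 7 fell and Aspa rose (0.37, SE 0.14). Their list had adjusted p = 1.4e-05, and adjusted p = 0.368 with an estimated correlation. The 3 measured blood genes fell (3 adjusted over the list alone), with Alas2 at -1.62 (SE 0.28), at adjusted p = 2.59e-05, and adjusted p = 0.167 with an estimated correlation. Oxidative phosphorylation genes fell in 12 of 77 (25 adjusted over the list alone), with Atp5g1 at -0.56 (SE 0.08), at adjusted p = 2.63e-09, and adjusted p = 0.424 with an estimated correlation. Pan-neuronal genes fell in 3 (Stmn2, Nefm and Tubb3) and rose in 1 (Syt1) of 12, with 4 and 1 adjusted over the list alone, at adjusted p = 0.0307, and adjusted p = 0.368 with an estimated correlation.

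The following lists did not pass between the ages. GnRH neuron markers had adjusted p = 0.145 and none of 4 called (1 adjusted over the list alone). Gnrh1 stood at 29.3 ± 5.32 CPM in adults and 20.01 ± 6.70 CPM in young (log2 0.58, SE 0.20, adjusted p = 0.0882), and Rpl10a differed by -0.22 (SE 0.10, adjusted p = 0.18). Of perineuronal net genes (adjusted p = 0.433) Hapln2 and Hapln4 rose and Hapln1 fell (-0.91, SE 0.26), with the same counts adjusted over the list alone. Of mural cell markers (0.468) Rgs5 fell (-0.90, SE 0.17), also adjusted over the list alone, and of nuclear long noncoding RNAs (0.468) Neat1 and Peg13 rose (2 up and 1 down adjusted over the list alone). Of cholesterol synthesis genes (0.906) Mvd and Hmgcs1 fell, also adjusted over the list alone, and the test pointed down while the median of the list was 0.06. Markers of GABA neurons (0.468), glutamate neurons (0.981), ependyma and choroid plexus (0.258), endothelium (0.981), fibroblasts and meninges (0.901), collagens (0.486) and immediate early genes (0.965) had no member past the threshold over all genes or adjusted over the list alone. Anterior pituitary genes were not measured in this fit.

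Between the ages 670 genes rose and 832 fell of 15938 in supernatant. The new pools alone, chosen as a subset after seeing the data, gave 481 genes and the prior pools alone 11. Of 478 genes called in the new pools and tested in the prior ones, 452 (94.6%) had the same sign there. The count was 655 without the term for pool origin, 256 in the negative controls alone and 2257 by DESeq2. It was 858, 723 and 928 without young negative pool 2, adult negative pool 1 and adult prior pool 3. Among the negative pools age could not be separated from genotype.

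**Figure D3:**
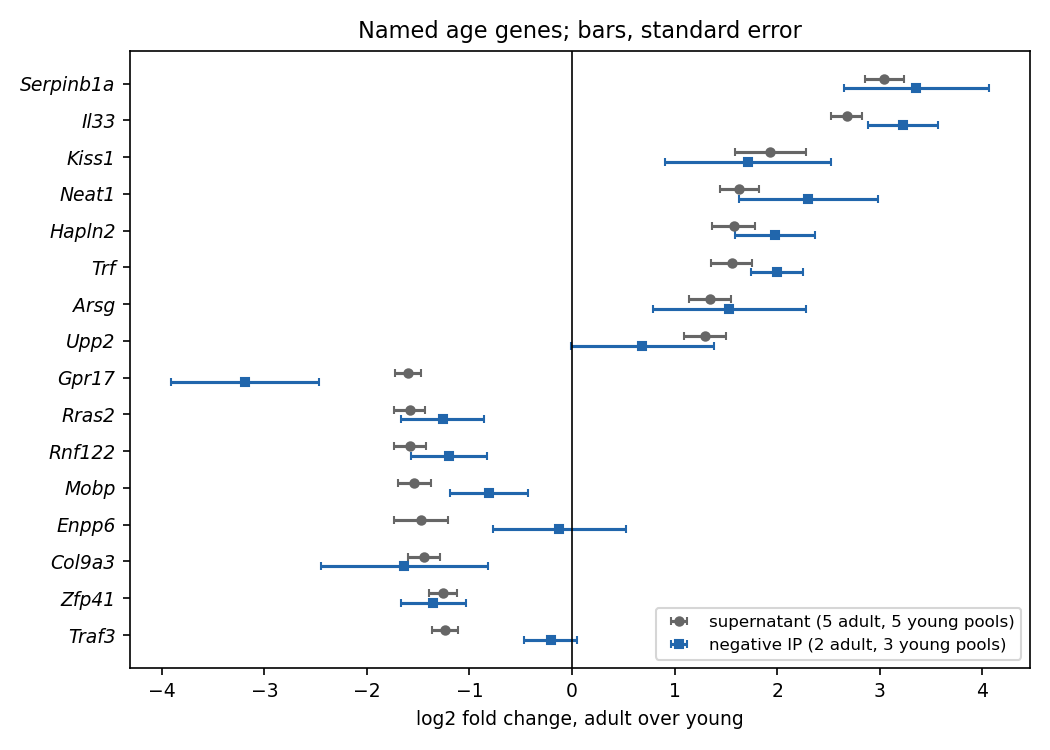
Log2 fold change of adult over young for the genes named in supernatant, with the standard error as bars; grey circles are supernatant (5 pools per age) and blue squares the negative IP (2 adult and 3 young pools). Il33 and Trf passed the threshold in both fractions, with log2 changes of 2.68 and 1.56 in supernatant and 3.22 and 2.00 in the IP.

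In the negative IP the age difference was measured over 2 adult and 3 young pools, and it cannot be separated from the genotype of these pools. Its p-values and standard errors rest on a spread estimated together with the supernatants of the same fit. Libraries of the same group correlated at 0.891 to 0.910 in the negative IP and at 0.970 to 0.990 in supernatant. The spread between IP pools may thus be understated, and the 5 negative IP libraries fitted alone called 0 genes, so the calls given here are uncertain. Il33 rose from 8.48 ± 3.81 to 78.9 ± 7.06 CPM (log2 3.22, SE 0.34, adjusted p = 0.0175), and the antigen presentation genes H2-Ab1 (3.16, SE 0.59) and Cd74 (2.43, SE 0.43) rose from 1.74 and 8.18 CPM to 15.5 and 44.0 CPM. Trf (2.00, SE 0.25), Daam2 (2.01, SE 0.38), Kctd9 (1.60, SE 0.24), Rab35 (1.54, SE 0.22) and the glycine transporter gene Slc6a9 (1.44, SE 0.24) also rose. Zfp691 (-2.09, SE 0.40), Rnf152 (-1.98, SE 0.33), Coro2a (-1.73, SE 0.33), Mycl1 (-1.67, SE 0.29), Gnb1 (-1.52, SE 0.29), Tusc1 (-1.51, SE 0.24), Lhfpl2 (-1.49, SE 0.28) and Med1 (-1.45, SE 0.20), a Mediator subunit gene, fell. Complement and MHC class I genes had no member past the threshold over all genes and 4 of 10 higher adjusted over the list alone (B2m at 1.02, SE 0.21; H2-T23 at 2.51, SE 0.58), with adjusted p = 9.94e-06, and adjusted p = 0.187 with an estimated correlation. Nefl (-1.18, SE 0.16) and Nefm (-0.85, SE 0.12) fell, and the pan-neuronal list (2 of 12 down; 3 down and 1 up adjusted over the list alone) had adjusted p = 0.0368, and adjusted p = 0.576 with an estimated correlation.

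Further lists passed in the negative IP without a single member past the threshold over all genes. Ribosomal proteins (median log2 0.47 over 78 genes, 0 adjusted over the list alone) had adjusted p = 1.35e-15, neuropeptides (0.68 over 24 genes, 2 up adjusted over the list alone) adjusted p = 0.000171, cholesterol synthesis (-0.27 over 14 genes, 2 down adjusted over the list alone) adjusted p = 0.00582 and the secretory pathway (0.41 over 12 genes, 0 adjusted over the list alone) adjusted p = 0.0103. Each of these 4 lists had adjusted p = 0.576 with an estimated correlation. Oxidative phosphorylation (median 0.16 over 77 genes, 0 adjusted over the list alone) had adjusted p = 0.0028, and adjusted p = 0.815 with an estimated correlation.

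Counts for age in the negative IP were 53 genes up and 66 down of 16361 by edgeR. Of the genes called for age in supernatant 41 were also called in the IP, all with the same sign, where independent lists would share 11.24. The fractions came from the same negative pools, so these were not independent comparisons. DESeq2 called 1284 genes, and limma voom and a fit of the 5 negative IP libraries alone called none, with 1484 and 1147 genes at an unadjusted p under 0.05. The edgeR count was 0 without any of the 3 young supernatants, 1 without either adult supernatant or adult IP 1, 458 without adult IP 2, and 241, 281 and 365 without young IP 1, 2 and 3.

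Prior pools were compared with new pools in supernatant as a check of batch, with 4 pools against 6 and age as a term. The chemokine gene Ccl19 stood at 2.61 ± 1.77 CPM in prior and 17.1 ± 8.97 CPM in new pools (log2 -2.65, SE 0.49, adjusted p = 0.00941), the stress-response gene Nupr1 fell by 2.03 on the log2 scale (SE 0.46) and the gap junction gene Gjb2 by 2.00 (SE 0.47). Nbl1 (-1.81, SE 0.34), Copz2 (-1.40, SE 0.31), Itih5 (-1.31, SE 0.30), the endothelial transcription factor gene Sox18 (-1.30, SE 0.34) and Rdm1 (-1.25, SE 0.16) were lower too. The imprinted noncoding RNA Meg3 was higher, at 562 ± 195 against 193 ± 74.8 CPM (1.55, SE 0.26), as were Lime1 (1.56, SE 0.21), Gpr165 (1.46, SE 0.27), Wsb1 (64.8 ± 19.0 against 29.2 ± 4.84 CPM), the immediate early gene Fos (1.11, SE 0.15), Cntnap4 (1.04, SE 0.16), AW551984 (1.00, SE 0.16) and Cacng5 (0.99, SE 0.15). Gnrh1 differed by -0.17 (SE 0.21, adjusted p = 0.61) and Rpl10a by -0.20 (SE 0.10, adjusted p = 0.196).

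Lists lower in the prior pools covered several cell types. Ribosomal proteins fell in 37 of 78 genes (64 adjusted over the list alone; adjusted p = 3.16e-22) and oxidative phosphorylation in 26 of 77, with Ndufs1 up (47 and 1 adjusted over the list alone; 4.74e-13). Microglia markers fell in 6 of 12 (6 adjusted over the list alone; 8.06e-07), led by Aif1 (-1.31, SE 0.21), and fibroblast and meningeal markers in 4 of 8 (8 adjusted over the list alone; 1.14e-05), such as Dcn (-1.72, SE 0.48). Endothelium fell in 1 of 10 (7 adjusted over the list alone; 0.000515), complement and MHC class I in 6 of 10 (6 adjusted over the list alone; 0.000521) and collagens in 3 of 13 (4 adjusted over the list alone; 0.000667). These 7 lists each had adjusted p = 0.345 with an estimated correlation. Astrocyte markers fell in 4 of 12 (6 adjusted over the list alone; 0.00022), S100b at -0.94 (SE 0.16), with adjusted p = 0.311 with an estimated correlation. Blood genes fell in 2 of 3 (3 adjusted over the list alone; 0.000515), with adjusted p = 0.314 with an estimated correlation. Mature oligodendrocyte genes fell in 2 of 12 (3 adjusted over the list alone; 0.000433), with adjusted p = 0.394 with an estimated correlation, and mural cell markers in 1 of 7 (1 adjusted over the list alone; 0.0321), with adjusted p = 0.413 with an estimated correlation. Oligodendrocyte precursor genes did not pass (1 of 8 down, 1 adjusted over the list alone; 0.497).

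Receptor, secretory and some other lists were higher in the prior pools. GABA-A receptor subunits rose in 7 of 14 (12 adjusted over the list alone; adjusted p = 6.28e-06), Gabrq most (log2 1.18, SE 0.23), glutamate receptor subunits in 5 of 15 (8 adjusted over the list alone; 0.000103), the secretory pathway in 6 of 12 (8 adjusted over the list alone; 0.000515) and nuclear long noncoding RNAs in 5 of 10 with Neat1 down (5 and 1 adjusted over the list alone; 0.00248). These 4 lists each had adjusted p = 0.345 with an estimated correlation. GABA neuron markers rose in 5 of 8 (6 adjusted over the list alone; 0.000311) and immediate early genes in 3 of 11 (7 adjusted over the list alone; 0.000187), both with adjusted p = 0.314 with an estimated correlation. Cholesterol synthesis genes rose in 3 of 14 (3 adjusted over the list alone; 0.0291), with adjusted p = 0.413 with an estimated correlation. Several neuronal lists did not pass: pan-neuronal genes (2 of 12 up, 3 adjusted over the list alone; 0.197), glutamate neurons (0 of 6, 1 adjusted over the list alone; 0.28), hypothalamic neuropeptides (0 of 24, 0 adjusted over the list alone; 0.365) and GnRH neuron markers (0 of 4, 0 adjusted over the list alone; 0.604).

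By origin 1052 genes were higher and 961 lower of 15938 by edgeR, and the rank correlation with transcript length was 0.445 across 10266 genes, which are not independent replicates. The count was 3081 by DESeq2 and 3070 by limma voom. It was 1039, 1072, 290, 1121 and 471 without young negative pool 2, adult negative pool 2, young prior pool 2, adult prior pool 3 and adult prior pool 4. Origin went with GFP status and genotype in every pool except the new GFP-positive one.

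The same RNA of 4 prior pools sequenced in both sets showed what a technical repeat changes. The ribosomal RNA precursor Rn45s rose from 709 ± 316 CPM in the first set to 6181 ± 477 CPM in the second (SD, n = 4; log2 3.24, SE 0.19), and Actb, the beta-actin gene often used as a reference, from 318 ± 23.3 to 1329 ± 70.4 CPM (2.06, SE 0.04, adjusted p = 2.39e-14). Cdr1, which cannot be told apart from its antisense RNA without strand, rose by 2.49 (SE 0.08), Eif4ebp2, which encodes a repressor of translation initiation, by 2.21 (SE 0.12), and the RNA helicase genes Dhx9 by 1.68 (SE 0.09) and Ddx6 by 1.44 (SE 0.06). Cnot6l (1.55, SE 0.11) and Zfp462 (1.48, SE 0.15) rose as well. Nptxr (-1.23, SE 0.16), Mink1 (-0.96, SE 0.11), Mmp15 (-0.93, SE 0.15), Solh (-0.92, SE 0.14), Dagla (-0.87, SE 0.16), Wscd2 (-0.84, SE 0.14), Mtap7d1 (-0.83, SE 0.06) and Caskin2 (-0.82, SE 0.12) fell. Gnrh1 stood at 24.1 CPM in the second set and 35.3 CPM in the first (-0.62, SE 0.10, adjusted p = 0.000257), and Rpl10a rose by 0.26 (SE 0.05).

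Ribosomal protein genes rose between the sets in 69 of 78 (72 adjusted over the list alone), with Rpl7 at 0.67 (SE 0.05), at adjusted p = 7.93e-46, and adjusted p = 0.354 with an estimated correlation. Oxidative phosphorylation genes rose in 48 of 77 with Uqcrc1 and Ndufb7 down (49 and 2 adjusted over the list alone), at adjusted p = 4.34e-13, and adjusted p = 0.55 with an estimated correlation. Nuclear long noncoding RNAs rose in 6 of 10, Xist at 1.78 (SE 0.23), with Peg13 down (6 and 1 adjusted over the list alone), at adjusted p = 3.54e-06, and GABA-A receptor subunits in 9 of 14 with Gabre down (9 and 1 adjusted over the list alone), at adjusted p = 0.00163. Both lists had adjusted p = 0.354 with an estimated correlation. The 3 anterior pituitary genes measured here, Gh, Prl and Lhb, gave adjusted p = 0.963, with none called over all genes or adjusted over the list alone. In all 2417 genes rose and 2591 fell of 16117 by edgeR, 147 of the rises and 15 of the falls by over 2-fold, and the fit without the pool as a term called 2262. Genes with lower GC content were higher in the second set, with a median log2 of 0.17 among those lowest in GC content and -0.23 among those highest (rank correlation -0.552 across 10214 genes, which are not independent replicates).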

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

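The tests of age by fraction and of single libraries apart from their group given here were planned. In young supernatant, Rras2 stood at 23.4 CPM (23.37) in young prior pool 2 and between 35.6 and 39.9 CPM in the other 4 young pools, so that this library lay apart from its group. In adult supernatant, Mobp stood at 322.07 CPM in adult negative pool 2 and between 151.92 and 194.99 CPM in the other 4 adult pools. These were the 2 of 63 values tested in which a library lay apart, and chance alone sets apart about 5%.

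The difference between IP and supernatant in the negative controls passed as different between ages for 4 gene groups at the preset correlation. In these pools age went with genotype. Adult minus young, the median log2 ratio differed by 0.44 over oxidative phosphorylation genes and by 0.409 over cytosolic ribosomal proteins. It differed by -0.455 over glutamate receptor subunits and by -0.317 over cholesterol synthesis genes. With an estimated correlation none of the 4 passed (adjusted p = 0.939, 0.939, 0.412 and 0.939), and no biological explanation was tested for them. The same difference ran with transcript length across genes, which are not independent replicates, with a rank correlation of -0.258.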

How the results depend on the processing

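The new pools alone for age and camera with the pool as a block were chosen after seeing the data; the other alternatives were planned. With RLE scaling and without the filter on low counts, every count of genes called by a test stayed within 1.5 times its value. The descriptive count was not repeated under these 2 settings. Over all alternatives, of 1738 repeats of named genes 1526 (87.8%) passed again, 212 did not and none changed sign. Named genes were chosen for groups that do not overlap in mostly the same libraries. A change of sign was therefore hardly possible, and its absence carries no weight. For age in the negative IP 97 of 240 passed again. DESeq2 called 2897 genes for IP against supernatant in adults, 118 for age by fraction, 1284 for age in the negative IP, 2257 for age in supernatant, 3081 for pool origin and 210 for the GFP-positive IP, and limma voom called 0 for age in the negative IP and 3070 for origin; the cause was not tested. For age in the negative IP, the fit of the 5 negative IP libraries alone called 0. It holds fewer samples, but the count was 241, 281 and 365 without young IP 1, 2 and 3. Without any of the 3 young supernatants, which enter the shared spread but not the contrast, it was 0. Each of these fits changed the number of libraries and the shared spread together, so the causes cannot be told apart. For age in supernatant the count was 655 without the term for origin, and 256, 11 and 481 in the negative controls, the prior pools and the new pools alone, which hold fewer samples. The fit of the sequencing sets with no replicate block, which leaves the differences between pools in the error, called 2262. The enrichment count of the GFP-positive IP was 74 at 4-fold (79 to 93 in the negative IP libraries) and 33 at 5 CPM or more (67 to 124), both stricter by construction. With an estimated correlation the number of lists called fell to 0 in every comparison. Leaving out 1 library at a time gave 3571 to 5725 genes for IP against supernatant, 2842 to 4856 in young, 285 to 2398 in adult, 0 to 67 for age by fraction, 0 to 458 for age in the negative IP, 723 to 1706 for age in supernatant, 290 to 2493 for origin, 3688 to 4851 for the sequencing sets and 0 to 1 for the GFP-positive IP. Some of these fits left an arm with 1 library, assumed to vary like the others. Some counts rose when a library was left out, so the smaller number of libraries is not the only cause, and no other cause was tested.

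With the pool as a replicate block, IP against supernatant gave 4970 genes, 4266 in young and 2075 in adult pools, and age by fraction gave 0; the lists called numbered 4, 3, 6 and 6. Beyond the list calls given with the results, the block changed no other call of a list. Young and adult pools shared only replicate numbers: deviations of same-numbered negative supernatants correlated at -0.064 and -0.019 across genes. A replicate block on those numbers gave 931 genes for age in supernatant. A fit that pairs the GFP-positive IP with its own supernatant was not run. At these depths a gene under the floor of 0.0594 to 0.108 CPM could not be told from absence of the transcript, and in the GFP-positive IP edgeR recovered 2% of simulated 2-fold and 49% of 4-fold changes, so most changes of that size would be missed or left uncertain there.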

Other observations

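The corrections for transcript length and GC content, the median change of called genes after them (added last) and the comparison of signs between new and prior pools were chosen only after the result was seen; the splits of the samples and the position of the GFP-positive pool were planned. In all, 41 genes were called and over 8-fold higher in the IP without the tag, and 35 of them exceeded 8-fold at both ages. Besides the genes named by rule, the following were chosen after their values were seen. They included the hedgehog transcription factor genes Gli2 (log2 5.01, SE 0.46; 34.2 against 1.00 CPM) and Gli3 (4.03, SE 0.32) and the nucleoporin genes Nup98 (4.91, SE 0.27) and Ranbp2 (3.69, SE 0.14). The histone demethylase gene Kdm6b (3.89, SE 0.23), the DNA demethylation gene Tet3 (3.12, SE 0.18) and the chromatin remodeller gene Chd7 (3.28, SE 0.18) were also among them. The neurofilament gene Nefh rose from 110 to 948 CPM (3.08, SE 0.10), with its partners Nefl and Nefm at 1.89 and 1.28. The median transcript of the 41 was 6768 nt long with a coding length of 4056 nt, against 3049 and 1368 nt over all genes tested. They were also richer in GC, with medians of 53.8% over the transcript and 58.3% over the coding part, against 50.2% and 53.4%. No list of chromatin or nuclear proteins was fixed beforehand, so no enrichment is claimed.

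A length trend may account for part of what the IP without the tag recovered. Length was that of the longest annotated transcript, so its correction may leave changes that the length of the expressed transcript would remove. With a spline trend on transcript length removed from each library, in the fit with the pool as a block, 51.7% of the called genes were kept with the same sign, only just above the bound of 50% set for excluding length as the whole cause, and the median change of the called genes went from log2 0.78 to 0.465 (median SE 0.13 before and after). Over all genes GC content showed no trend to remove (rank correlation -0.005), which argues against it as the whole cause, and the 94.2% kept after its correction adds nothing. The 8 rises named by rule stayed between log2 4.81 (Rai1) and 6.02 (Prr12) after the length correction, while Rps29 moved from -1.68 to -0.67. Binding of long mRNA to the beads or antibody and the smaller number of genes with a count in the IP libraries stay open as causes, and no biological explanation was tested.

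Base composition may likewise account for part of the difference between sequencing sets on the same RNA. With a GC trend removed per library, 56.1% of the calls were kept and the rank correlation with GC content went from -0.552 to 0.017, while Actb stayed at log2 2.08; a length trend left 78.2%. The median change of the called genes went from log2 0.341 to 0.245 and to 0.298 (median SE 0.07 in each). These values argue against GC content or length of the annotated transcript as the whole cause. Library preparation of the sets stays open, since the labels used here do not separate it from sequencing. No biological difference applies, because the RNA was the same.

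The difference between prior and new pools could stem from transcript length, GFP status or handling. With a length trend removed 36.8% of the calls were kept, short of the bound of 50%, but the median change of the 1994 called genes went only from log2 0.434 to 0.338 (median SE 0.102 and 0.097), and 99.4% kept their sign. The calls ended because somewhat smaller changes no longer passed (lost calls from 0.382 to 0.252). These values argue against the annotated length as the whole cause and leave it open as a part. A gap between annotated and expressed length could also leave such changes, so the correction cannot exclude length itself. On a scale from 0 at the adult negative pools to 1 at the adult prior pools, the new GFP-positive pool lay at 0.34, and the adult negative pools themselves lay at 0.302 and -0.287 and the prior ones at 0.756 and 1.12. With 1 such pool, and with a doubt in the series text over whether it or the adult negative pool at 0.302 carried the tag, GFP status and origin cannot be told apart.

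The age differences in supernatant may be shared by independent mice. Of the genes called in the new pools, 94.6% had the same sign in the prior pools, taken to be separate mice, against 70.6% over all genes at 8 CPM or more; fold changes of the called genes correlated at 0.778 across genes, which are not independent replicates. Since new and prior pools were all collected at the same ages, age effects and anything else that always differed between the age groups stay open together.

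Exchanging labels tested how often other groupings of the libraries called as many genes. For IP against supernatant, 1 of 60 splits of the labels within age called as many genes, the real one with 5246, and no other split called any. The IP and supernatant of a pool pair, however, and the 16 splits that part every pair, with 0 in all but the real one, are too few for a share under 0.05. For age in supernatant, 1 of 60 splits called as many, the real one with 1502 against 1 at most in the others, and for origin 1 of the 100 splits within age, the real one with 2013 against 51 at most. For age and origin these are the smallest shares that the splits allow, both under 0.05, which makes chance unlikely without excluding it. The other splits leave the real difference in the error, which lowers their counts. The young pools allow 10 splits, with 4428 genes in the real one and 0 in the others, and the sequencing sets 8, with 5008 and 0; these are too few for a share under 0.05.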
